A study of Rattus norvegicus with 11 samples.

How the data were processed

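RNA from the left kidney of 11 rats was measured on an Affymetrix array, 1 array per rat. The rats were Sprague Dawley (SD) or Dahl SS/Jr (SS, a strain bred for salt-sensitive hypertension) and had eaten food with 0.3% NaCl (low salt) or 8.0% NaCl (high salt) for 10 days. The labels gave 3 SD rats on low salt, 3 SD rats on high salt, 3 SS rats on low salt and 2 SS rats on high salt (rats 1 and 3). The deposited table holds 1 intensity per probe set and array, on a linear scale. How the authors summarised and normalised the probes, and with which software, is not given in the sources used here. The 2%-trimmed means of the deposited arrays ran from 306 to 406, so the arrays did not share 1 target over the probe sets in the table. They split by strain without overlap, from 306 to 331 in SD rats and from 344 to 406 in SS rats. The scaling is therefore confounded with strain.

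The table held 5382 probe sets. The 59 control probe sets were left out, and the remaining 5323 were matched to genes through the array annotation, which gave 1 symbol to 4557 of them, several to 210 and none to 556. Current gene names were taken from RefSeq on the rat assembly GRCr8, used for names alone, and no coordinates are given. Each array was multiplied by a factor, from 0.841 to 1.12, that brought its 2%-trimmed mean to 342. Values under the pooled 30th percentile of all arrays, an intensity of 101, were set to that floor, and log2 was taken, which puts the floor at 6.65. Probe sets above the floor on at least 2 arrays were tested, which were 4130 probe sets of 2677 named genes.

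Each comparison came from 1 limma fit (lmFit and eBayes) of the 4 group means, with 7 residual and 2.77 prior degrees of freedom, two-sided moderated statistics and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at an adjusted p under 0.05. The 6 contrasts were high minus low salt in SD, the same in SS, the mean of both, SS minus SD on low salt, SS minus SD on high salt, and the SS diet difference minus the SD diet difference. P-values measure the spread between rats within groups, and the number of arrays limits the precision. The labels name no batch.

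Gene lists of pathways, transport systems, nephron segments and other cell types were written before the data were examined, as were the tests and the rule for named genes. Of the 33 lists, 32 had at least 5 tested genes, each gene standing with its probe set of highest mean value. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, with camera at an estimated correlation and fry beside it. The rule named, in each contrast, the 10 genes with the largest rise and the 10 with the largest fall among called probe sets with 1 symbol whose groups did not overlap. The groups' overlap was not asked for in the averaged and interaction contrasts. Each gene stood with its probe set of smallest p, and where fewer than 5 genes passed, the 5 with the smallest p were added as values. Up to 4 members of each list described were named too, and a fixed set of genes of blood pressure control whatever their values. Of that set, Agt and Cyp4a2 were not analysed here.

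The alternatives were quantile normalization, the values as deposited with no scaling, a floor at the 10th percentile, a pseudocount of 16 in place of the floor, no filter, a filter at the 60th percentile, eBayes with trend and robust, a fit of only the groups compared, a block for rat number, array weights, a threshold of 0.1 and each array left out in turn. For lists, fry, an estimated correlation and the mean of a gene's probe sets were tried. Chosen after seeing the data were the fits without arrays that stood apart and camera on z-transformed statistics.

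The fit was tested on simulated data, drawn as normal noise with each probe set's mean and residual spread, with known changes added to 1 group. After the filter, 3985, 3968, 3971 and 3964 simulated probe sets were tested for diet in SD, diet in SS, strain on low salt and strain on high salt. A change of 2-fold was recovered in 69.7%, 67.7%, 77.3% and 68.8% of the changed probe sets of these comparisons, in that order. For a change of 1.5-fold the shares were 34.3%, 25.8%, 40% and 16.4%. Of the probe sets called in the simulations, 11 of 135, 13 of 133, 7 of 133 and 5 of 112 had no change added. Computations used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures used Python 3.11.15 with matplotlib 3.10.9.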

Results

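The 11 arrays profiled the left kidney of SD and SS rats after 10 days on 0.3% or 8.0% NaCl. There were 3 rats in each group except SS on high salt, which had 2. The comparisons address how dietary salt and strain relate to kidney gene expression. Differences are log2 values with their standard errors, and group levels are mean log2 intensities with SD. A group whose arrays all lay at the floor of 6.65 gives a difference that is a lower limit in size.

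Some arrays stood apart from the rest, and the genes behind this were measured. SS rat 2 on low salt correlated with no other array above 0.870, while each other array reached at least 0.960 with another. The highest correlation of any pair, 0.986, joined SS rat 1 on low salt and SS rat 3 on high salt. The 2 SS rats on high salt correlated at 0.965. In SS rat 2 on low salt, genes of the liver outside the acute phase had a median 1.90 above the mean of the other arrays over 24 genes. Adipose tissue markers had one of 2.63 over 9 genes. Its proximal tubule markers lay at -0.79 over 23 genes and its collecting duct markers at -0.58 over 13. In SD rats 1 and 2 on low salt, the 2 haemoglobin genes lay at -3.55 and -3.42, while the other arrays ran from 0.13 to 1.41. The actin 3' to 5' ratio, a sign of RNA integrity, was 2.09 ± 0.22 (SD, n = 3) in SD on low salt, 1.5 ± 0.13 (n = 3) in SD on high salt, 1.67 ± 0.23 (n = 3) in SS on low salt and 1.58 ± 0.004 (n = 2) in SS on high salt. The GAPDH 3' to 5' ratio separated the strains without overlap, from 1.23 to 1.42 in SD rats and from 1.12 to 1.18 in SS rats. Counts are therefore also given without these 3 arrays, a setting chosen after seeing the data.

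**Figure D1:**
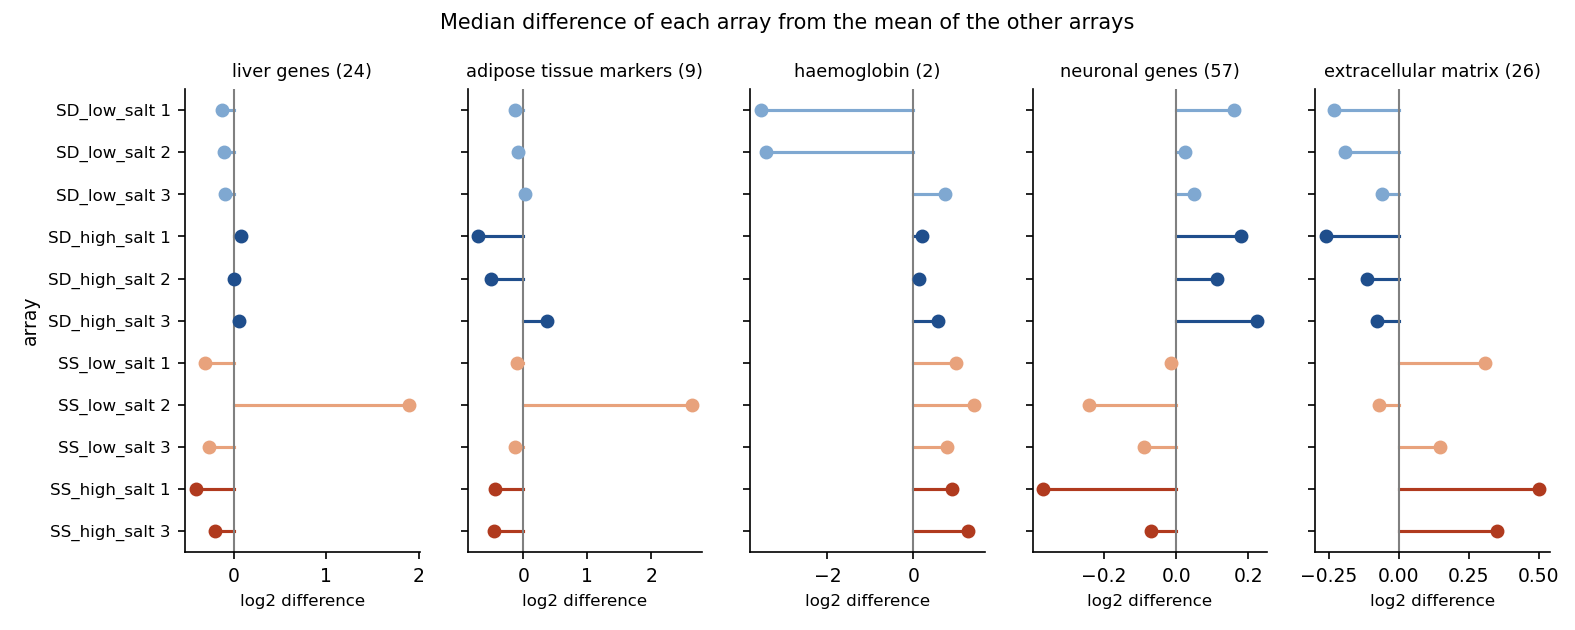
Median log2 difference of each array from the mean of the other arrays (horizontal axis) for liver genes, adipose tissue markers, haemoglobin genes, neuronal genes and extracellular matrix genes, with 1 point per array and the arrays ordered by group. SS rat 2 on low salt lies at 1.90 for liver genes and 2.63 for adipose markers, and SD rats 1 and 2 on low salt lie at -3.55 and -3.42 for haemoglobin.

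In SD rats, Sgk1, Ces1e and 1 of the 2 probe sets of Ier3 were lower on high salt. Sgk1, the aldosterone-induced kinase that raises sodium uptake in the distal nephron, fell by 1.5 ± 0.18 (adjusted p = 0.0159), from 9.0 ± 0.27 to 7.51 ± 0.16 (SD, n = 3 and 3). Ces1e, a carboxylesterase, fell by 1.46 ± 0.18 (adjusted p = 0.0159), from 8.19 ± 0.24 to 6.72 ± 0.12, with 2 of the 3 high-salt rats at the floor. Ier3, an immediate early gene of cell survival, fell by 0.99 ± 0.11 on the probe set of smallest p (adjusted p = 0.0159), while its other probe set rose by 0.29 (adjusted p = 0.379). On each of these 3 lowered probe sets the groups did not overlap. The actin 3' to 5' ratio separated the same groups, from 1.85 to 2.29 on low salt and from 1.37 to 1.64 on high salt. The GAPDH ratio overlapped between them. RNA integrity thus cannot be fully told apart from diet in SD. The next smallest p-values belonged to Isl2, at no less than 1.19 ± 0.18 with all low-salt SD rats at the floor, and Anpep, the brush border aminopeptidase, at 2.04 ± 0.32, both with an adjusted p of 0.0547, and the other probe sets of Anpep gave 0.31 and 1.08.

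Among the gene lists in SD, genes of xenobiotic conjugation lay lower on high salt, with a median of -0.29 over 24 genes, 18 of them negative (adjusted p = 0.0254; adjusted p = 0.723 with an estimated correlation). None of the 24 was called, over all probe sets or adjusted over the list alone. Ces1d, another carboxylesterase, had a value of -1.70 ± 0.53 and Gstm1, a glutathione transferase, one of -1.22 ± 0.66. The heat shock and unfolded protein response list had a median of -0.23 over 17 genes, 13 of them negative (adjusted p = 0.0254; adjusted p = 0.723 with an estimated correlation). Of these genes 0 were called over all probe sets and 2 were lower when adjusted over the list alone. Ddit3, a transcription factor of endoplasmic reticulum stress, had a value of -0.83 ± 0.20, and Hspa5, the main chaperone of that compartment, one of -0.73 ± 0.20. Ribosomal protein genes had a median of -0.17, with 20 of 23 negative (adjusted p = 0.000706; adjusted p = 0.81 with an estimated correlation), and none was called in either way.

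The 3 SD probe sets came from limma, against 631 at an unadjusted p under 0.05, where 206.5 were to be expected by chance. The groups did not overlap in 981 probe sets, or 23.8%, where chance gives 10%. Leaving out the 3 arrays that stood apart left 0 probe sets called, with 1 low-salt SD rat and larger errors, at -1.19 ± 0.23 for Sgk1 (adjusted p = 0.293), -1.71 ± 0.25 for Ces1e and -1.03 ± 0.16 for Ier3 (adjusted p = 0.239 for both). Single arrays moved the count too, to 1 without SD rat 1 on low salt, 0 without SD rat 2, 43 without SD rat 3, 0 without SD rat 1 or SD rat 2 on high salt, 6 without SD rat 3 on high salt, and 5 and 12 without SS rats 1 and 2 on low salt. The xenobiotic list had an adjusted p of 0.119, 0.099 and 0.665 without SD rats 1 and 3 on low salt and SD rat 3 on high salt, and 0.318 without the 3 arrays. It also lost its call with quantile normalization (0.0546), no scaling (0.0569), no filter (0.12), the stricter filter (0.159) and the mean of a gene's probe sets (0.063). The heat shock list had 0.1 and 0.366 without SD rat 1 on low salt and SD rat 3 on high salt, and the ribosomal list 0.108 without the latter. The heat shock list also had 0.0546 with quantile normalization, 0.0578 with no filter, 0.159 with the stricter filter, 0.134 in a fit of only the groups compared and 0.194 with array weights. These lists had an adjusted p of 0.745 and 0.318 without the 3 arrays. Ace, Agtr1a, Nos3, Edn1, Hsd11b2, Acsm3, Spp1 and Klk1, genes of blood pressure control or of kidney injury, had SD diet values from -0.09 to 0.51 and adjusted p-values from 0.296 to 0.969.

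In SS rats, high salt raised Cdk1 and Ier3. Cdk1, the kinase that drives entry into mitosis, rose by 1.04 ± 0.10 (adjusted p = 0.00385), from 6.66 ± 0.01 (SD, n = 3), with 2 of the 3 low-salt rats at the floor, to 7.70 ± 0.09 (n = 2). All SD rats lay at the floor as well, so the error and p of Cdk1 rest on a spread that the floor keeps small. Ier3 rose by 0.92 ± 0.12 (adjusted p = 0.0499) on its probe set of smallest p and gave 0.01 on the other. The next smallest p-values belonged to Cxcl10, an interferon-induced chemokine, at 0.56 (adjusted p = 0.29), Aif1, a macrophage gene, at 0.77, and Dusp6, a phosphatase of the MAP kinase ERK, at 0.90 ± 0.18 (adjusted p = 0.316 for both).

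Extracellular matrix genes lay higher on high salt in SS, with 22 of 26 positive and a median of 0.22 (adjusted p = 0.0126; adjusted p = 0.477 with an estimated correlation). Col12a1, a collagen, had a value of 0.81 and Tgfb1, the profibrotic growth factor, one of 0.67 ± 0.17. Smooth muscle, mesangium and fibroblast markers had a median of 0.21, with 12 of 13 positive (adjusted p = 0.0427; adjusted p = 0.503 with an estimated correlation). They share Dcn, Col1a1 and Col3a1, among others, with the matrix list. The heat shock list had a median of 0.28, with 14 of 17 positive (adjusted p = 0.0428; adjusted p = 0.503 with an estimated correlation), and Hspa1a, an inducible chaperone, had a value of 0.76 ± 0.22. Oxidative phosphorylation and citrate cycle genes had a median of 0.18, with 20 of 24 positive (adjusted p = 0.0427; adjusted p = 0.477 with an estimated correlation). Ribosomal protein genes had a median of 0.13, with 21 of 23 positive (adjusted p = 0.0428; adjusted p = 0.567 with an estimated correlation). Adipose tissue markers had a median of -1.08, with 8 of 9 negative (adjusted p = 0.0126; adjusted p = 0.477 with an estimated correlation), and Scd, the stearoyl-CoA desaturase, a value of -2.99 ± 0.89. Fatty acid oxidation genes had a median of -0.12, with 24 of 35 negative (adjusted p = 0.0427; adjusted p = 0.503 with an estimated correlation). No member of these lists was called, over all probe sets or adjusted over the list alone. SS rat 2 on low salt, whose adipose and liver genes lay above those of the other arrays, is in the low-salt group of each of these medians.

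The 2 SS probe sets came from limma, against 295 at an unadjusted p under 0.05, and groups did not overlap in 811 probe sets, or 19.6%, where chance gives 20%. Without the 3 arrays that stood apart 0 probe sets were called, while Cdk1 kept its size with a larger error, at 1.03 ± 0.13 (adjusted p = 0.221), as did Ier3, at 0.90 ± 0.14 (adjusted p = 0.524). With a floor at the 10th percentile Cdk1 had one of 0.608, and it lost its call in 6 of 22 settings. Ier3 lost its call in 21 of 22 settings, and among the arrays left out singly its highest adjusted p was 0.327. The count was 1 without any of the 6 SD rats or without SS rat 2 on low salt, and 2 without any other rat. The matrix list had an adjusted p of 0.0873 and 0.241 without SS rat 3 on low salt and on high salt. The oxidative phosphorylation list had 0.0831 and 0.0872 without SS rats 1 and 3 on low salt and 0.372 and 0.0611 without SS rats 1 and 3 on high salt. The smooth muscle list had 0.0606 and 0.0938 without SS rats 2 and 3 on low salt and 0.368 without SS rat 3 on high salt. The adipose list had 0.36 without SS rat 2 on low salt, 0.241 without SS rat 3 on high salt and 0.0669 without the 3 arrays. The fatty acid oxidation list turned direction without SS rat 2 on low salt (adjusted p = 0.765), and had 0.661 without SS rat 3 on high salt.

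The heat shock list in SS had an adjusted p of 0.0562 without SD rat 1 on high salt, 0.0937 and 0.0938 without SS rats 1 and 3 on low salt, and 0.346 and 0.0611 without SS rats 1 and 3 on high salt. The ribosomal list in SS had one of 0.0503 without SD rat 3 on high salt, 0.218 and 0.0785 without SS rats 2 and 3 on low salt, 0.241 without SS rat 3 on high salt and 0.181 without the 3 arrays. Of 27 settings, the SS diet call was lost in 5 for the matrix list, 7 for adipose markers and 8 for oxidative phosphorylation. It was lost in 9 for smooth muscle markers, 10 for ribosomal proteins, 12 for heat shock and 13 for fatty acid oxidation. Among the heat shock losses were no scaling (adjusted p = 0.056) and the floor at the 10th percentile (0.0571). The genes of blood pressure control and kidney injury had SS diet values from -0.17 for Klk1 to 0.59 for Spp1, the osteopontin gene, with adjusted p-values from 0.688 to 1.

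Averaged over both strains, high salt changed 0 probe sets by limma, against 327 at an unadjusted p under 0.05. The smallest p belonged to Cdk1, at 0.52 ± 0.06 (adjusted p = 0.052). For Cdk1 all SD rats lay at the floor on both diets, so its averaged value came from SS alone. Next were Anpep at 1.41 ± 0.24 and Dusp6 at 0.69 (adjusted p = 0.274 for both). They were followed by Drd3, a dopamine receptor, at 0.65 and Cd55, a complement inhibitor, at 0.72 (adjusted p = 0.326 for both). Fatty acid oxidation genes had an averaged median of -0.14 (adjusted p = 0.00166), adipose markers one of -0.65 (adjusted p = 0.0166), xenobiotic genes one of -0.15 (adjusted p = 0.0282) and amino acid metabolism genes one of -0.07 (adjusted p = 0.0417). Smooth muscle markers had 0.27 (adjusted p = 0.0187) and immune genes 0.10 (adjusted p = 0.0219). Each of these 6 lists had an adjusted p of 0.527 with an estimated correlation. Adjusted over the list alone, 2 immune genes were higher and 1 amino acid gene lower, against 0 over all probe sets. Without SS rat 3 on high salt each of the 6 lists lost its call, with adjusted p-values from 0.264 to 0.421. Without SS rat 2 on low salt the adipose list had one of 0.185, the fatty acid oxidation and amino acid lists 0.112 and the xenobiotic list 0.06. Without SD rat 3 on high salt the xenobiotic list had 0.449, the immune and amino acid lists 0.0677 and the smooth muscle list 0.0834. Without SS rat 3 on low salt the immune list had 0.0739, the smooth muscle list 0.0689 and the amino acid list 0.0623. The xenobiotic and smooth muscle lists had 0.0962 and 0.0626 without SD rat 1 on low salt, and the xenobiotic and amino acid lists 0.0725 and 0.0773 without SD rat 3 on low salt. The amino acid list had 0.119 and 0.126 without SD rat 2 on low salt and SD rat 1 on high salt. With all 3 arrays that stood apart left out, 5 of these lists lost their call, with adjusted p-values from 0.276 to 0.534, and the adipose list had 0.0462. Given camera on z-transformed statistics the amino acid list had an adjusted p of 0.054. Of 26 settings it lost its call in 20, among them quantile normalization (adjusted p = 0.206) and no scaling (0.0904). The xenobiotic list lost its call in 14, among them quantile normalization (0.103) and no scaling (0.0873). The losses were 6 for fatty acid oxidation, 7 for adipose markers, 8 for immune genes and 10 for smooth muscle markers. The averaged count was 10 without SD rat 3 on low salt and 1 without SS rat 1 on low salt or SS rat 3 on high salt. The averaged values of the blood pressure genes ran from -0.01 for Hsd11b2 to 0.46 for Acsm3.

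The diet change differed between the strains for Ier3, and Cdk1 passed the same test. Ier3 differed by 1.91 ± 0.16 (adjusted p = 0.0021), falling in SD and rising in SS on that probe set, although its other probe set gave -0.29. Cdk1 gave 1.04 ± 0.13 (adjusted p = 0.026), but all SD rats lay at the floor on both diets. Its diet change in SD was not measured. Its call was lost in 14 of 21 settings, among them the floor at the 10th percentile (adjusted p = 0.269) and 9 of 11 settings with a single rat left out (highest adjusted p = 0.123). Among those 11 it kept its call without SD rat 3 on low salt or SS rat 1 on high salt. Sgk1, at 1.79 ± 0.28, Ces1e, at 1.72 ± 0.26, and Grm7, a glutamate receptor, at -3.00 ± 0.44, each had an adjusted p of 0.0636 for this difference. Heat shock genes had a median difference of 0.62, with 13 of 17 positive (adjusted p = 0.00315; adjusted p = 0.463 with an estimated correlation), and 3 were higher adjusted over the list alone, against 0 over all probe sets. Ddit3, at the floor in SD on high salt, had a value of 1.39, Hspa1a of 1.19 and Hspa5 of 1.01. Ribosomal protein genes had a median difference of 0.28, with 22 of 23 positive (adjusted p = 0.000226; adjusted p = 0.463 with an estimated correlation) and none called. Without the 3 arrays that stood apart, 0 probe sets differed, Ier3 kept its size with a larger error, at 1.92 ± 0.21 (adjusted p = 0.109), and the heat shock list had an adjusted p of 0.0846 and the ribosomal list 0.0701. The count of 2, beside 581 at an unadjusted p under 0.05, became 17 without SD rat 3 on low salt, 4 without SS rat 1 or 3 on high salt, and 1 without any of the other rats except SS rat 3 on low salt, where it was 2. Across all probe sets the diet differences of SD and SS had a Pearson r of -0.09 and a Spearman rho of -0.18, over genes, which are not independent replicates.

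**Figure D2:**
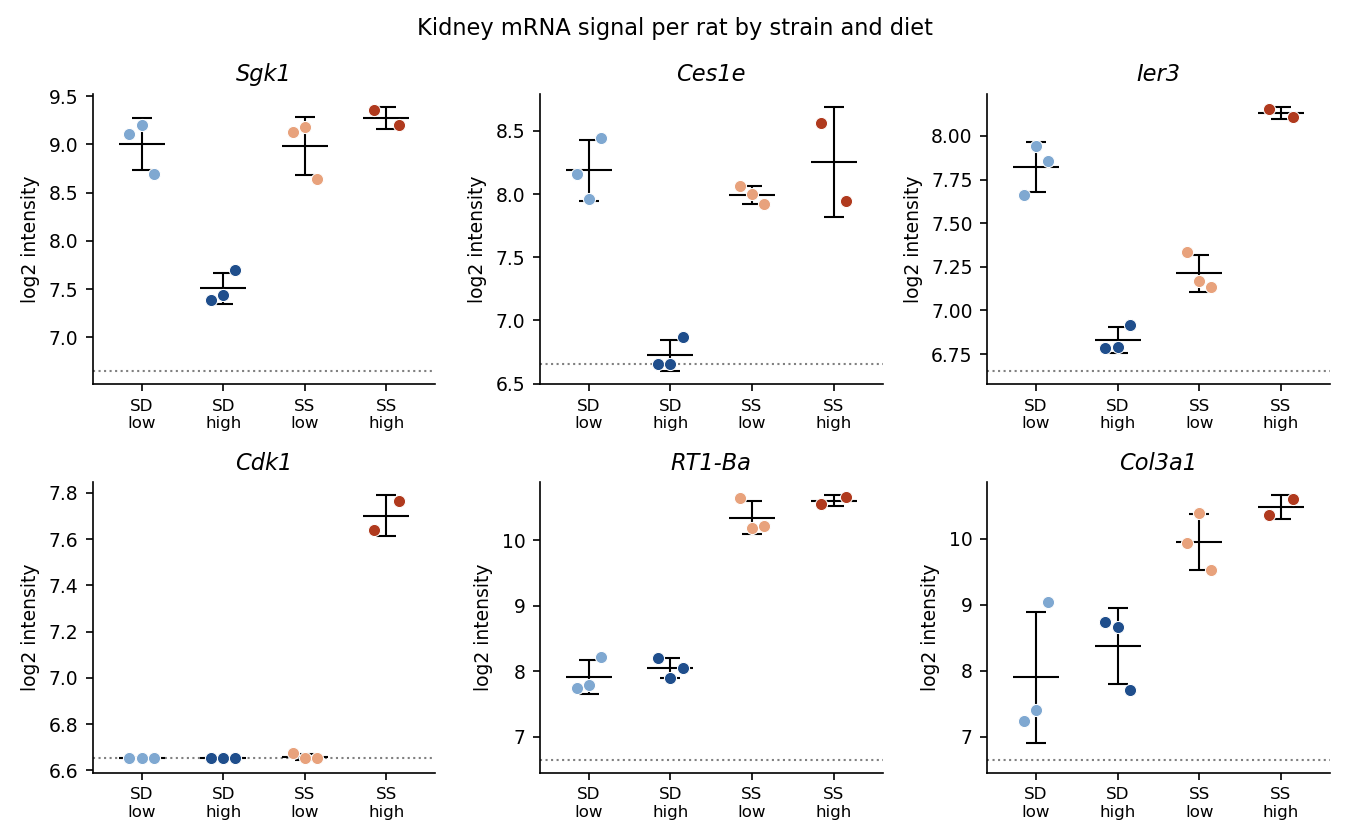
Log2 intensity (vertical axis) of Sgk1, Ces1e, Ier3, Cdk1, RT1-Ba and Col3a1 in each rat of the 4 groups, with 1 point per rat, bars for the group mean ± SD and a dotted line at the floor of 6.65. Sgk1 averages 9.0 in SD on low salt and 7.51 in SD on high salt, and Cdk1 leaves the floor in SS on high salt.

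On low salt, the genes that differed between SS and SD kidneys included RT1-Ba, RT1-Bb, Col3a1, Ehhadh and Slc13a2. RT1-Ba, an alpha chain of the class II molecules that present antigen, was higher in SS by 2.43 ± 0.17 (adjusted p = 0.000285), at 10.35 ± 0.25 against 7.91 ± 0.26 (SD, n = 3 and 3). Its other probe sets gave 0.33 and 0.79, of which the latter was called. RT1-Bb, its partner chain, was higher by at least 1.65 ± 0.18 (adjusted p = 0.00672), with SD at the floor, while its other probe sets ran from -0.53 to 0.34. Col3a1, a fibrillar collagen, was higher by 2.05 ± 0.46 (adjusted p = 0.0497), and gave 0.65 on its other probe set. With the 3 arrays that stood apart left out these values were 0.69 ± 0.42 (adjusted p = 0.66) and 0.09. Ehhadh, an enzyme of peroxisomal fatty acid oxidation, was lower by -1.81 ± 0.20 (adjusted p = 0.00672), and Slc13a2, the citrate transporter of the proximal tubule, by -1.41 ± 0.24 (adjusted p = 0.0269). The fatty acid oxidation list, which holds Ehhadh, was not called (median 0.12, adjusted p = 0.477).

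Further genes higher in SS on low salt were Anpep at 1.60 ± 0.32, with -0.31 and 0.52 on its other probe sets, Slc6a11, a GABA transporter, at 1.46, C1qb, a complement chain made by macrophages, at 1.40 ± 0.20 and at 0.79 on its other probe set, Isl2 at no less than 1.37 with SD at the floor, and Rgs14 at 1.25. The class II genes RT1-Da and RT1-Db1 were higher by 1.27 and 1.25. Lower in SS were Dnase1, a secreted nuclease, at -1.82 ± 0.32 and at -1.61 on its other probe set, Glyatl2 by at least -1.61 with SS at the floor, Cd80, a costimulatory molecule, at -1.61, Sec31a at -1.41, Dnase1l3 at -1.32, Klf9, a glucocorticoid-induced transcription factor, at -1.11 ± 0.14 and at -0.87 on its other probe set, and Muc1 at -1.02. Sod1, the cytosolic superoxide dismutase, was lower by -1.40 ± 0.18 on 1 probe set and had -0.11 and 0.38 on the others. Of 43 called genes with several probe sets, 5 had another called in the same direction and 12 had another of opposite sign.

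Of 26 matrix genes on low salt, 2 were higher in SS over all probe sets and 7 adjusted over the list alone, none lower (median 0.26, adjusted p = 0.00111; adjusted p = 0.669 with an estimated correlation). Dcn, the proteoglycan decorin, was higher by 1.18 ± 0.23, and Col1a1 and Sparc had values of 2.06 and 1.37 (adjusted p = 0.052 and 0.0826). Of 44 immune genes 6 were higher in SS over all probe sets, and 8 higher and 2 lower adjusted over the list alone, around a median of 0.05 (adjusted p = 0.00891; adjusted p = 0.669 with an estimated correlation). Those 6 were RT1-Ba, RT1-Db1, C1qb, Cd53, a leukocyte surface protein, at 0.95, Csf1, the macrophage growth factor, at 0.81, and Mx1, an interferon-induced gene, at no less than 0.78 with SD at the floor. Smooth muscle, mesangium and fibroblast markers had a median of 0.33, with 2 of 13 higher and 4 adjusted over the list alone (adjusted p = 0.00891; adjusted p = 0.734 with an estimated correlation). Those 2, Dcn and Col3a1, were also the 2 called matrix genes, so the results of these lists are not separate evidence. Agtr1a, the angiotensin receptor, had a value of 0.57 ± 0.14 (adjusted p = 0.0564), and Acsm3, a candidate gene of hypertension once named SA, one of -0.90 ± 0.21 (adjusted p = 0.052). Ace, Nos3, Edn1, Hsd11b2, Spp1 and Klk1 had values from -0.32 to 0.24.

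On low salt limma called 116 probe sets, 52 higher and 64 lower in SS, or 44.8% higher, with 96 named genes among them. With no scaling 205 were called, 86.3% of them higher, while the median difference of all probe sets went from -0.04 to 0.12 on low salt and from -0.07 to 0.06 on high salt. The deposited trimmed mean was higher in each SS rat than in each SD rat, so array intensity and strain cannot be told apart here. The directions given for lists held under each scaling, but of the 27 list calls in all comparisons 5 ended with quantile normalization and 10 with no scaling. The groups did not overlap in 1207 probe sets, or 29.2%, where chance gives 10%. Without the 3 arrays that stood apart, 2 probe sets were called, RT1-Ba (adjusted p = 0.0346) and RT1-Bb (adjusted p = 0.0245), the matrix list had an adjusted p of 0.0418, the immune list 0.169 and the smooth muscle list 0.157. Only 1 probe set was called without SD rat 1 or SD rat 2 on low salt, 13 without SD rat 2 on high salt, and 9 and 57 without SS rats 1 and 3 on low salt. Each named gene here except RT1-Ba lost its call without SD rat 1 or SD rat 2 on low salt. Besides Col3a1, the values of 5 named genes moved by over 1.5 times without the 3 arrays, to 0.86 for C1qb, 0.76 for RT1-Da, -1.02 for Dnase1, -0.70 for Slc13a2 and -0.80 for Dnase1l3.

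On high salt, SS kidneys differed from SD kidneys in 516 probe sets. The count on low salt was 116, and the difference of the counts was not tested. Their order turned with array weights, at 687 on high and 778 on low salt, and without SS rat 1 on high salt, at 9 and 104. RT1-Ba was higher in SS by 2.56 ± 0.19 (adjusted p = 0.000505), with 0.28 and 0.46 on its other probe sets, and RT1-Bb by at least 2.49 ± 0.21 (adjusted p = 0.000687), although another probe set of RT1-Bb was lower by at least -1.60 with SS at the floor (adjusted p = 0.0326). Sgk1 was higher by 1.77 ± 0.21 (adjusted p = 0.00416), at 9.28 ± 0.11 (SD, n = 2) against 7.51 ± 0.16 (n = 3). Dcn was higher by 1.84 ± 0.26 (adjusted p = 0.00788), with 0.88 and 1.19 on its other probe sets. Col3a1 was higher by 2.11 ± 0.52, with 0.63 on its other probe set (adjusted p = 0.139). Pck1, the rate-limiting enzyme of gluconeogenesis, was lower by -1.33 ± 0.31 (adjusted p = 0.0283), and Nos1, the neuronal nitric oxide synthase that the macula densa also makes, by -1.22 ± 0.22 (adjusted p = 0.0129).

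Also higher in SS on high salt were Id3, a transcriptional inhibitor, at 2.20 ± 0.36, Egr1, an immediate early transcription factor, at 2.02 ± 0.36 and at -0.25 on its other probe set, Nupr1, a stress-response gene, at 1.74, Sec11a at 1.65, and Aif1 at no less than 1.64 ± 0.18 with SD at the floor, while its other probe sets gave -0.20 and 0.77. Also lower were Lipf, gastric lipase, by at least -3.38 ± 0.58 with SS on high salt at the floor, the neurotransmitter receptor genes Grm7 at -1.79 and Chrm1 at -1.47, Map6, a microtubule protein of neurons, at -1.40 ± 0.16, Oaz2 at -1.35, Spink1 at -1.30 and Tsga10 at -1.30. Sod1 was lower by -1.35, with -0.10 and 0.75 on its other probe sets. Of 156 called genes with several probe sets, 22 had another called in the same direction and 47 had another of opposite sign.

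Matrix genes lay higher in SS on high salt, with 22 of 26 positive, 8 higher over all probe sets and 12 adjusted over the list alone, none lower (median 0.52, adjusted p = 1.43e-05; adjusted p = 0.345 with an estimated correlation). Among the 8, Serpinh1, the collagen chaperone, was higher by 1.13, Mmp14, a membrane metalloproteinase, by 1.06, and Fn1, fibronectin, by 1.57, with -0.05 and 0.17 on its other probe sets. Of 21 tubular injury genes 5 were higher and 1 lower, and 7 and 1 adjusted over the list alone (median 0.44, adjusted p = 0.00134; adjusted p = 0.345 with an estimated correlation). These included S100a10 at 1.45, Anxa1 at 1.13 and Vim, a mesenchymal intermediate filament, at 1.04, while Gsta1 was at -0.39. Of 17 heat shock genes 3 were higher, and 4 adjusted over the list alone (median 0.63, adjusted p = 0.00226; adjusted p = 0.345 with an estimated correlation), namely Hspa5 at 1.19, Hspa1a at 1.13 and Ddit3 at no less than 1.09 over all probe sets. Of 13 smooth muscle, mesangium and fibroblast markers 3 were higher, and 8 higher and 2 lower adjusted over the list alone (median 0.56, adjusted p = 0.0125; adjusted p = 0.459 with an estimated correlation). The 3 were Tpm4, Dcn and Col3a1, of which Dcn and Col3a1 are among the called matrix genes too. Of 44 immune genes 6 were higher, and 9 higher and 1 lower adjusted over the list alone (median 0.03, adjusted p = 0.0279; adjusted p = 0.459 with an estimated correlation), among them Cd53 at 1.35, Nfkbia at 1.08 and Mx1 at 0.90. Of 23 ribosomal protein genes 3 were higher, and 4 adjusted over the list alone (median 0.14, adjusted p = 0.0125; adjusted p = 0.708 with an estimated correlation).

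Gluconeogenesis and glycolysis genes were lower on balance in SS on high salt by fry (adjusted p = 0.00086), with 5 of 24 lower over all probe sets, and 6 lower and 1 higher adjusted over the list alone, around a median of -0.29. Besides Pck1 these included Pklr, a pyruvate kinase, at -0.91 and Hk2, a hexokinase, at -0.51. Camera, which compares the list with other genes, gave this list an adjusted p of 0.122. Of the genes of salt handling and blood pressure, Agtr1a was higher by 0.72 ± 0.15 (adjusted p = 0.0205) and Slc12a2, a sodium, potassium and chloride cotransporter, by 0.86 ± 0.16 (adjusted p = 0.0147), the 1 called gene of 25 in the sodium and chloride transport list, which was not called (median 0.05, adjusted p = 0.815). Acsm3 was lower by -1.01 ± 0.23 (adjusted p = 0.0275) and Guca2b, the natriuretic peptide uroguanylin, by -1.0 (adjusted p = 0.0123). Of the antioxidant enzymes, Cat, catalase, was lower by -0.86 (adjusted p = 0.00953) and Gpx3, the plasma glutathione peroxidase made by the kidney, by -0.62 (adjusted p = 0.0274), the 2 called genes of 20 in a list that was not called (median 0.03, adjusted p = 0.882). Skeletal muscle markers had a median of -0.67, with 5 of 5 negative (adjusted p = 0.114). Of these 2 were called lower, Pygm, a glycogen phosphorylase, at -0.90 with 0.08 on its other probe set, and Tnni2, a troponin, at -0.67. These salt handling, antioxidant and muscle genes were chosen after their values were seen.

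On high salt limma called 516 probe sets, 259 higher and 257 lower in SS, or 50.2% higher, and 547 with no scaling, 85.9% of them higher. The groups did not overlap in 2035 probe sets, or 49.3%, where chance gives 20%. The 3 arrays that stood apart are in neither group, but they bear on the spread, the floor and the filter. With them left out, 549 of 4074 probe sets were called, 410 of them among the 516 of 4130. The GAPDH 3' to 5' ratio was 1.30 ± 0.06 (SD, n = 3) in SD and 1.13 ± 0.02 (n = 2) in SS on high salt. The count was 9 without SS rat 1 on high salt, which leaves 1 array in that group that is assumed to vary like the other groups, 301 without SD rat 2 on low salt, 175 and 136 without SD rats 1 and 2 on high salt, 586 without SS rat 3 on high salt, 358 of them among the 516, and 807 without SS rat 2 on low salt. Without SS rat 1 on high salt Sgk1 gave 1.69 ± 0.27 (adjusted p = 0.0655), near its size with all arrays, while RT1-Ba, RT1-Bb, Aif1, Map6 and Egr1 kept their calls. The immune list had an adjusted p of 0.1, 0.0508 and 0.355 without SD rat 3 on high salt, SS rat 3 on low salt and SS rat 3 on high salt, and 0.0633 with camera on z-transformed statistics. Without SS rat 3 on high salt the tubular injury list had 0.0508, the smooth muscle list 0.193 and the ribosomal list 0.0761, and the ribosomal list had 0.1 without SD rat 3 on high salt.

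**Figure D3:**
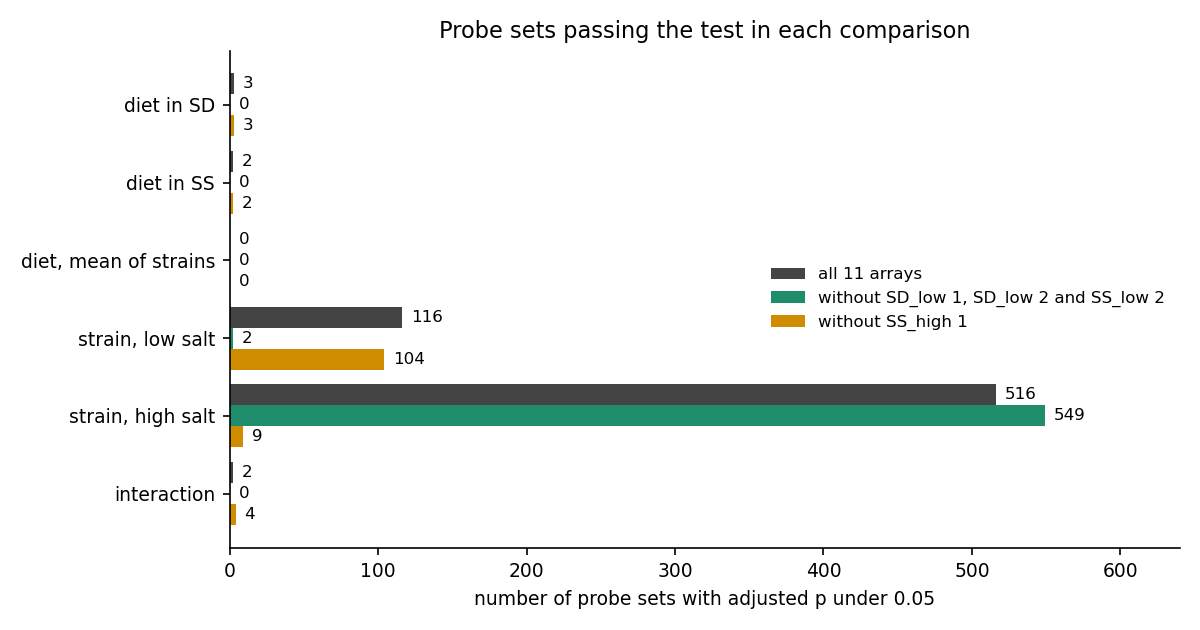
Number of probe sets with an adjusted p under 0.05 (horizontal axis, from 0) in each comparison with all 11 arrays, without SD rats 1 and 2 and SS rat 2 on low salt, and without SS rat 1 on high salt. The strain count on low salt goes from 116 to 2 and 104, and that on high salt from 516 to 549 and 9.

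**Figure D4:**
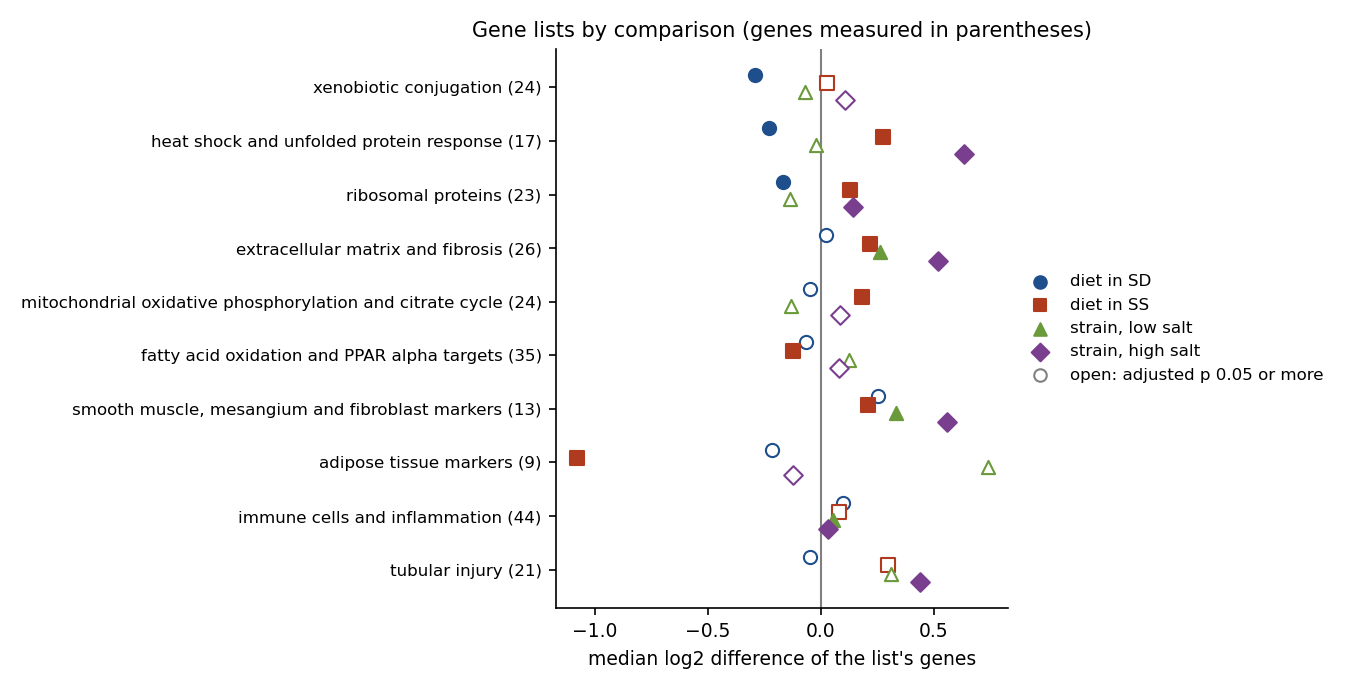
Median log2 difference (horizontal axis) of each gene list called in at least 1 of 4 comparisons, with filled points at an adjusted p under 0.05 by camera with its preset correlation. Matrix genes have medians of 0.26 and 0.52 for SS minus SD on low and high salt and 0.22 for diet in SS, and no list passes with an estimated correlation.

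The strain differences were shared in part between the diets, which have no arrays in common. Of the 116 probe sets called on low salt 48 were called in the same direction on high salt, 27 higher and 21 lower in SS, where independent lists would share 3.26 and 3.98. Both sets of calls came from 1 fit, with 1 spread per probe set and the same floor and filter, so they are not independent. The sign was the same on high salt for 109 of the 116. With all arrays, RT1-Ba, RT1-Bb, Dcn, Mx1 and Cd53 were among the genes higher in SS on both diets, and Sod1 was lower on both on 1 probe set. Ier3 alone was called in opposite directions, lower in SS on low salt by -0.61 ± 0.11 (adjusted p = 0.0269) and higher on high salt by 1.30 ± 0.12 (adjusted p = 0.00119), while its other probe set gave -0.03 and -0.32. Over all probe sets the strain differences on low and high salt had a Pearson r of 0.38 and a Spearman rho of 0.37 across genes, which are not independent replicates.

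**Figure D5:**
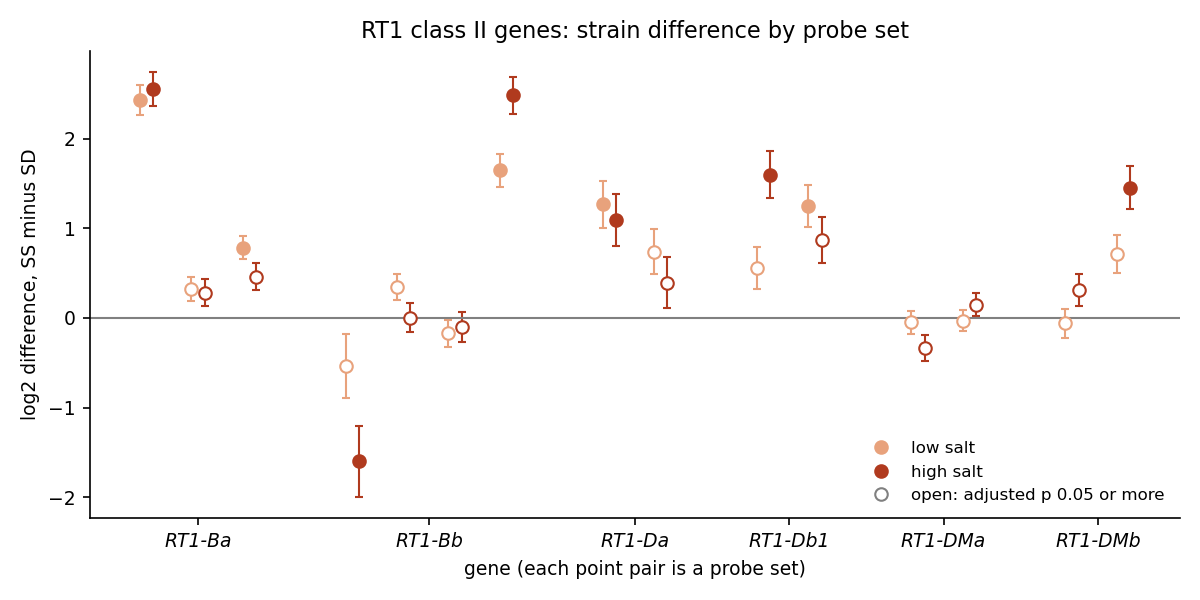
SS minus SD log2 difference (± SE) of each probe set of 6 RT1 class II genes on low and on high salt, with filled points at an adjusted p under 0.05. The highest RT1-Ba probe set lies at 2.43 and 2.56, and the probe sets of RT1-Bb lie on both sides of 0.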

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

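The interaction contrast was planned, and the tests that weigh explanations here were chosen after the results were seen. The list of neuronal genes was also added after seeing the data, but its test was written before the values of its genes were looked at. The interaction contrast, which tests whether the diet change differs between strains, passed for 2 genes and 2 lists. Ier3 differed by 1.91 on the log2 scale on 1 probe set and by -0.29 on the other. Cdk1 gave 1.04, a value set by the floor in SD, where all rats lay at it on both diets. The lists differed, the heat shock and unfolded protein response list by a median of 0.62 and the ribosomal protein list by a median of 0.28. Neither list passed with an estimated correlation (adjusted p = 0.463 for both).

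SS rat 2 on low salt stood apart from the other 10 arrays, and an acute-phase response of the kidney is argued against by liver genes outside the acute phase, whose median over 34 genes lay 2.01 above the other arrays. Array-wide intensity differences left by the scaling are argued against as the source of the liver signal. There, 24 liver genes not looked at before lay 2.06 above other genes of the same level. The medians of those other genes over 1000 draws had a mean of -0.17 (SD 0.06). For its low correlation with other arrays, differences in the arrays' intensity distributions were not settled as a source. Quantile normalization gives all arrays the same distribution, and the highest correlation of this array went from 0.870 to 0.869. Each other array still reached at least 0.959 with another. The correlation thus stayed low with equal distributions. The test was set to decide only if that correlation moved by more, so it gives no verdict. A candidate explanation is liver RNA mixed into the sample, since the median of the same 24 genes was 1.90, against at most 0.07 on another array. With each probe set compared with itself, Gc was at 12.13 against a mean of 8.23 on the others and Apoc3 at 11.87 against 8.84, while Apoa1 was at 11.82 against 6.80 on 1 probe set and at the floor against 9.27 on the other, and 29 of the 34 genes were higher on this array and 21 above the floor on each of the others. Adipose markers at 2.63 were not tested under that explanation. Besides the acute-phase response no biological explanation was tested, since this rat's group has no design difference from its 2 fellows.

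RT1 class II genes were higher in SS on some probe sets and not on others. More antigen-presenting cells in SS kidneys are argued against as the whole source of the highest probe sets of RT1-Ba and RT1-Bb, at 2.56 and at least 2.49 on high salt, by Cd74, RT1-DMa, RT1-DMb, C1qb and Aif1, whose 13 probe sets had a median of 0.30 (SD 0.66), while for RT1-Da and RT1-Db1, at 1.10 and 1.60, they stay open. RT1-DMb, C1qb and Aif1 reached 1.45, 1.41 and 1.64 but gave 0.32 for RT1-DMb, 0.30 for C1qb and -0.20 and 0.77 for Aif1 on their other probe sets, and 9 macrophage genes outside RT1 that had not been looked at had a median of 0.02 (SD 0.53) on high salt and 0.08 (SD 0.34) on low salt. The 3 arrays that stood apart are not in the high-salt groups. On low salt, leaving them out left 1 SD rat, so only sizes are given for that fit. The highest probe sets of RT1-Ba and RT1-Bb had 2.21 and at least 1.89 without them. These sizes argue against the 3 arrays as their source, as far as 1 SD rat can show. For the other 3 probe sets higher on low salt the 3 arrays stay open. Each kept most of its size, from 0.79 ± 0.13 to 0.58 for RT1-Ba. RT1-Da went from 1.27 ± 0.26 to 0.76 and RT1-Db1 from 1.25 ± 0.23 to 0.90. Strain variants that bind the probes differently remain a candidate explanation, since in 2 of 6 genes the probe sets differed by over 1 log2 at both diets, by 2.10 ± 0.11 and 2.28 ± 0.12 in RT1-Ba and by 2.19 ± 0.45 and 4.08 ± 0.50 in RT1-Bb, and a strain difference in transcription stays open too, since no test separates it from variants.

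The strain difference on high salt covered 516 probe sets, among them genes with known functions in neurons and 2 of 5 skeletal muscle markers, which had a median of -0.67 as a list (adjusted p = 0.114). Array-wide intensity differences left by the scaling are argued against as the source of the size of this count, since quantile normalization gave 543. The count does not speak to which probe sets or directions hold. With no scaling most of the calls were higher in SS, as given above, so the directions did depend on the scaling. Signal from transcripts the kidney hardly expresses, differing between arrays, may account for part of the pattern, as 57 neuronal genes that had not been looked at had a median strain difference of -0.38, with 53 of them negative (camera p = 1.2e-05; p = 0.103 with an estimated correlation). Against the mean of the other arrays, these genes lay at -0.37 in SS rat 1 and -0.07 in SS rat 3 on high salt. In the SD rats on high salt they lay from 0.11 to 0.22. Muscle markers lay at -0.53 and -0.15 in the same 2 SS rats, so SS rat 1 weighs more in both medians. The median level of the neuronal genes, 7.93, lay near that of all genes, 8.04. Of the 57, 41 lay above the floor on each array, so low expression was not shown for them. The strain itself, as a biological difference, stays open, as does RNA quality, since the GAPDH 3' to 5' ratio was 1.30 ± 0.06 in SD and 1.13 ± 0.02 in SS.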

How the results depend on the processing

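The fits without arrays that stood apart and camera on z-transformed statistics were chosen after seeing the data. Counts are given for diet in SD (3 probe sets with all arrays), diet in SS (2), averaged diet (0), strain on low salt (116), strain on high salt (516) and the interaction (2), where they moved by over 1.5 times. The cause of these moves was not tested, except that a stricter filter tests fewer probe sets and leaving arrays out uses fewer rats.

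Quantile normalization gave 5 for diet in SD, 1 for diet in SS and 1 for averaged diet. With no scaling diet in SD gave 6, diet in SS 1 and strain on low salt 205. A floor at the 10th percentile gave 11 for diet in SD, 0 for diet in SS and 1 for the interaction. A pseudocount of 16 gave 9 for diet in SD, 0 for diet in SS and 1 for averaged diet. No filter gave 6 for diet in SD, 7 for diet in SS and 4 for averaged diet. The stricter filter gave 1 for diet in SD, 0 for diet in SS, 63 and 282 for strain on low and high salt, and 0 for the interaction. Trend and robust gave 9 for diet in SD, 1 for diet in SS and 1 for averaged diet. A fit of only the groups compared gave 10 for diet in SD, 0 for diet in SS, and 7 and 81 for strain on low and high salt. Array weights gave 430 for diet in SD, 1 for diet in SS, 1 for averaged diet, 778 for strain on low salt and 9 for the interaction. A threshold of 0.1 gave 10 for diet in SD, 1 for averaged diet, 373 and 957 for strain on low and high salt, and 5 for the interaction.

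Rat numbers mark different rats, and a block for the number gave 1 for diet in SD, 0 for diet in SS, and 5 and 239 for strain on low and high salt. The residuals of the 15 pairs with the same number had a mean r of -0.008 and those of the 30 with different numbers one of 0.004. Without SD rats 1 and 2 on low salt the counts were 0 for diet in SD, 0 for diet in SS, 0 and 185 for strain on low and high salt, and 0 for the interaction. Without these and SS rat 2 on low salt they were 0 for diet in SD, 0 for diet in SS, 2 for strain on low salt and 0 for the interaction. With each array left out in turn, they ran from 0 to 43 for diet in SD, 1 to 2 for diet in SS, 0 to 10 for averaged diet, 1 to 131 and 9 to 807 for strain on low and high salt, and 1 to 17 for the interaction.

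The fatty acid oxidation list for diet in SS turned direction with array weights (adjusted p = 0.954), without SS rat 2 on low salt (adjusted p = 0.765) and without the 3 arrays (adjusted p = 0.613), and with single arrays left out its adjusted p ran from 0.00023 to 0.765. Of the tests of called lists with an array left out, 239 kept their call, 57 lost it in the same direction and 1 lost it while turning direction. Under the other settings 281 kept it, 141 lost it in the same direction and 2 lost it while turning direction. All 27 list calls ended with an estimated correlation, 25 with fry and 2 with z-transformed statistics. Of these 27, 13 ended with array weights, 11 with no filter, 11 with the stricter filter, 10 with no scaling, 6 with a floor at the 10th percentile and 5 with quantile normalization. Of the tests of called named genes, 708 kept and 414 lost their call with an array left out, and 849 kept and 343 lost it otherwise. Signal near the floor of 6.65 limits the size of differences that can be read.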

Other observations

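The cell cycle and interferon lists described here, and the splits of arrays, were chosen after seeing the data, and Cdk1 and 4 interferon-induced genes had been seen by then. Cell cycle genes lay higher on high salt in SS rats, with a median of 0.30 over 11 genes (adjusted p = 1.77e-07; adjusted p = 0.189 with an estimated correlation; fry adjusted p = 0.0122). Without Cdk1 the other 10 genes had a median of 0.29, with 7 positive (camera p = 0.00119; p = 0.0744 with an estimated correlation). Cdk1, the mitotic kinase, was the 1 called over all probe sets, and 3 were higher adjusted over the list alone. Pcna, the sliding clamp of DNA replication, had values of 1.01 and 0.84 on its probe sets (adjusted p = 0.378 and 0.56). SS kidneys on high salt also had 3 cell cycle genes above SD, and 4 adjusted over the list alone, with a median of 0.23 (adjusted p = 0.000653; adjusted p = 0.207 with an estimated correlation), among them Pcna at 1.28 (adjusted p = 0.0126). The strain comparison had an adjusted p of 0.0504 without SS rat 3 on high salt, and a camera p of 0.0207 without Cdk1 (p = 0.157 with an estimated correlation).

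Interferon-induced genes as a list were higher in SS than in SD on both diets, on high salt through genes that had been seen. On high salt 5 of 15 were higher, and 6 higher and 1 lower adjusted over the list alone, with a median of 0.35 (adjusted p = 0.000653; adjusted p = 0.185 with an estimated correlation; fry adjusted p = 0.000922). Mx1, an antiviral GTPase, was higher by 0.90 and Psmb9, an immunoproteasome subunit, by 0.63, while Irf1 was higher by 1.17 on 1 probe set and had -0.57 on another. On low salt 2 of the 15 were higher, and 4 adjusted over the list alone, with a median of 0.15 (adjusted p = 0.000702; adjusted p = 0.112 with an estimated correlation; fry adjusted p = 0.00313). The 11 genes that had not been seen had a median of 0.08 on high salt (camera p = 0.147) and of 0.15 on low salt (camera p = 0.00856; p = 0.029 with an estimated correlation). Without the 3 arrays that stood apart, the list had an adjusted p of 0.00462 on high salt and 0.0259 on low salt.

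Other splits of the arrays were fitted for 3 comparisons. For diet in SD the 10 splits of 6 arrays are too few for a share under 0.05, with 3 probe sets in the real split and 0 as the highest other. For strain on low salt the 10 splits are also too few, with 116 in the real split and 53 in the highest other, which put SS rat 2 with SD rats 1 and 2. For averaged diet the real split gave 0 probe sets, which 100 of 100 splits within strains reach whatever their values, so that the count says nothing about chance, and the highest other gave 2.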
